A study of Oryza sativa with 4 samples.

How the data were processed

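Total RNA from rice leaves was labelled with biotin after one-cycle cDNA synthesis and hybridised to Affymetrix rice arrays, per the labels' protocols, which also state RNA integrity numbers above 8. The 4 samples are 2 biological replicates under 30% CO2 and 2 controls, each from the leaves of 10 plants grown under 16 h of light and 8 h of dark and kept for 6 h in the dark at 27 ± 2 °C, per the labels' protocols. Treated plants stood in sealed bags into which CO2 was injected. Whether control plants were also bagged is not stated. The labels name no date, scan or batch.

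The deposited values are log2 signals per probe set, 1 column per sample, and the labels name RMA and limma as the processing tools without versions. Values ran from 1.50 to 13.88 and the medians of the samples were 3.92, 3.88, 3.85 and 3.86. No rescaling was applied. The table holds 57194 probe sets and 0 of the array's control probe sets, so the planned comparison of 3' and 5' control signals could not be made. Signal over background is not given, and the number of arrays limits the precision.

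Probe sets were named through the array annotation table, updated by gene identifier through a table of rice genes (assembly ASM3414082v1, used for names only). Of the probe sets, 22436 had 1 gene, 95 had several and were not named, and 34663 are unnamed here. The 22436 probe sets covered 17905 genes, all of which matched the gene table, and 2457 of these have a name other than a clone or locus identifier. A gene was represented by its probe set with the highest mean over the 4 samples. Of 3444 genes with over 1 probe set, 1026 had a probe set past the threshold and 8 had probe sets called in both directions. Probe sets ending in _x_at or _s_at, which can bind several transcripts, numbered 9969 and represent 26 of the 139 genes selected for naming.

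Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block and no filter), with Benjamini-Hochberg adjustment over all probe sets and a threshold of adjusted p 0.05. A second count required a change of at least 2-fold. For genes, the same p-values were adjusted again over the 17905 representative probe sets, and adjusted p-values given for single genes are these. The residual degrees of freedom were 2 and the prior added 2.85. Log2 fold changes are CO2 minus control, with limma's standard error. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

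Before the data were examined, 39 themes of gene lists, the tests, the alternatives and the rule for named genes were fixed. The themes were written as patterns on gene descriptions, and the supplied tables hold symbols and synonyms without descriptions. The patterns were therefore rewritten for symbols after the tables were seen and before any fold change was computed. A gene without a name could not enter a list, so lists may hold only part of a family or theme. The guard cell list has no member, and 2 others have under 5, so that 36 lists were tested with camera at a preset correlation of 0.01, adjusted over these lists, with an estimated correlation and fry beside it. Camera compares a list with all other genes, whose mean need not be 0, while fry tests a list against no change. With an estimated correlation, camera gave 0 lists an unadjusted p under 0.05, so this version cannot decide on a single list. Most of the other genes have no name. Of the called genes 45.7% of those with a name were higher, against 38.7% of those without, which may favour calls of higher lists. In 10 lists, all of them not called, the median, the mean and camera's direction differ in sign. These are Calvin cycle, bicarbonate and organic acid enzymes, glutathione S-transferases, ethylene, abscisic acid and dehydration, auxin, gibberellin and cytokinin, cell wall growth, dividing cells, and epidermis and cuticle.

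Named genes were chosen by rule: the 12 largest rises and the 12 largest falls among named genes past the threshold with both samples of one group above both of the other, up to 4 members past the threshold per list by size of change (or the 2 with the smallest p where none passed), and the genes of fermentation. The rule asked for genes with a description, and a gene with a name took that place.

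The procedure was tested on simulated data with the controls' mean signals and with variances drawn from the fitted prior, without correlation between genes. With 200 changed probe sets among 57194, the simulated comparison recovered 0% of those changed 2-fold and 63% of those changed 4-fold, with 4 false calls among 67. With as many changed as were called here, 6583, it recovered 79.3%, and 4.55% of its calls were false. These 6583 took the fold changes estimated for the called probe sets, already large enough to be called, so 79.3% may be too high. Camera called 5 of 5 shifted lists and 1 of 20 unshifted ones. As the simulated genes were independent, this does not cover lists whose members vary together.

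The alternatives were the replicate number as a block, centring on each sample's median, a further quantile normalization, a filter at the median level, leaving out the _x_at and _s_at probe sets, a variance prior with an intensity trend or robust, thresholds of 0.01 and 0.1, limma's treat against 1.5-fold, the mean of a gene's probe sets, other set tests, and leaving out each sample. Same-numbered samples are not stated to share a batch.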

Results

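Gene expression was measured on Affymetrix rice arrays in the leaves of young rice plants (cultivar Senia, second vegetative stage) that had spent 6 h in the dark at 27 °C. Plants of the treated group were enclosed in sealed bags in which CO2 was raised to 30%, and control plants stayed in air labelled 0.04% CO2. Each group had 2 biological replicates, each made from the leaves of 10 plants. The value table held 57194 probe sets per sample, with medians between 3.85 and 3.92 on the log2 scale. Across probe sets, Pearson's r was 0.989 between the CO2 replicates, 0.993 between the controls and 0.951 to 0.968 between groups (probe sets are not independent replicates). The first principal component, with 81.4% of the variance, parted the groups. On it the CO2 replicates lay at 98.69 and 62.65, so that replicate 1 was further from the controls at -78.01 and -83.33.

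The single comparison of the design asks how rice leaves respond to a CO2 level far above that of air. The largest measured changes of named genes were in ethanol fermentation, where PDC1 (LOC4339066), a gene for the pyruvate decarboxylase that starts the pathway, rose 270.3-fold and ADH2 (LOC4350054), an alcohol dehydrogenase gene, rose 134-fold, both from control signals not shown to be above background, so that the exact folds are uncertain. Several genes of glycolysis, small heat shock proteins, nonsymbiotic hemoglobins and jasmonate repressors rose too. Genes that fell included those for a catalase, for protochlorophyllide reductase, for an ethylene receptor and for a glycolate oxidase, the last on a probe set that can bind several transcripts. So did 12 of 30 defence genes (4 rose) and 17 of 56 metal handling genes (4 rose), though neither list was called in a test against all other genes. In limma's test 6583 of the 57194 probe sets passed an adjusted p of 0.05, of which 2706 were higher and 3877 lower under 30% CO2. Of these, 4331 changed at least 2-fold (1834 higher and 2497 lower). Counted as genes, 2218 rose and 3369 fell out of 17905, and 808 of the genes that passed carry a name in the tables used. Among the 100 genes with the largest changes past the threshold, 87 rose and 83 have no name.

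**Figure D1:**
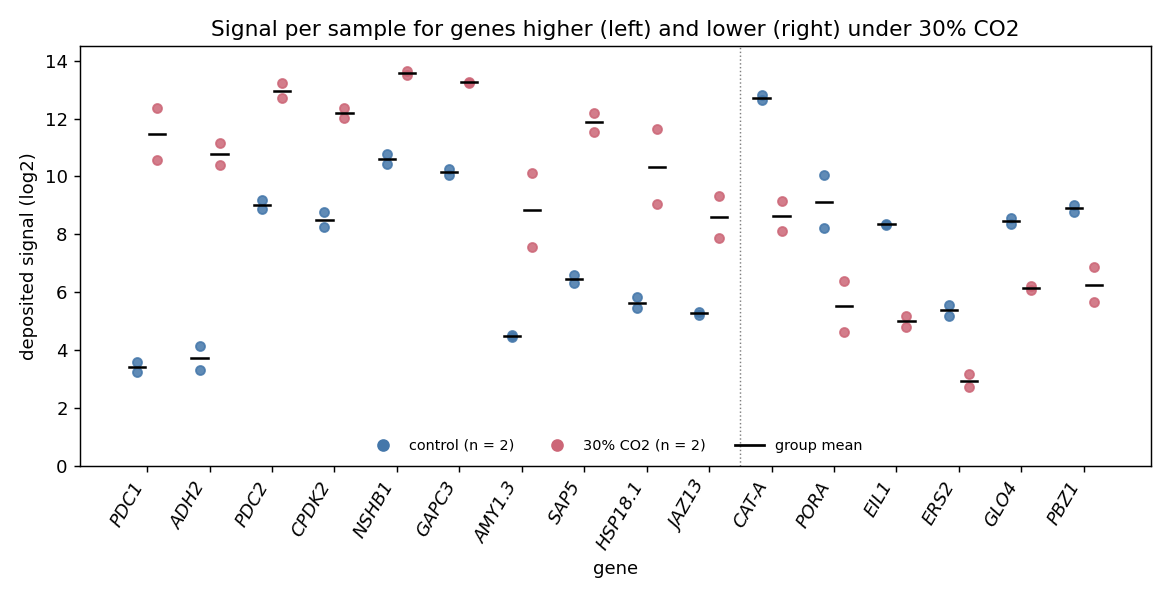
Deposited log2 signal (vertical axis) of 16 genes (horizontal axis) in each sample, with 2 control samples and 2 samples under 30% CO2 per gene as points and the group mean as a line. For every gene shown, both CO2 samples lay on the same side of both controls, from PDC1 at 3.40 in controls and 11.47 under CO2 to CAT-A at 12.73 and 8.62.

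Fermentation genes rose in both CO2 samples. The mean log2 signal of PDC1 was 3.40 ± 0.24 in controls (SD, n = 2) and 11.47 ± 1.28 under 30% CO2, a log2 fold change of 8.08 ± 0.60 (SE; adjusted p = 0.00282, limma). ADH2 went from 3.72 ± 0.60 to 10.78 ± 0.53, a log2 fold change of 7.06 ± 0.38 (adjusted p = 0.00224). The signals of both genes in controls were in the lower part of all probe sets, at the 42.6th and 47.9th percentile, and the table gives no detection calls. PDC2 (LOC4332519), already at 9.03 ± 0.22 in controls, rose to 12.97 ± 0.38 (log2 fold change 3.95 ± 0.23, adjusted p = 0.00239). The fourth member of the list, PDC3, did not pass over all genes (0.37 ± 0.12, adjusted p = 0.0747), so that 3 of 4 members rose, and 4 rose adjusted over the list alone.

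In the list of other genes known to respond to low oxygen, 3 of 5 members rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone. CPDK2, which encodes a pyruvate phosphate dikinase, rose by 3.69 on the log2 scale, on its only probe set, which can bind several transcripts. Without such sets 2 of 4 members rose and 1 fell. The nonsymbiotic hemoglobin genes NSHB1 and NSHB2 rose by 2.98 and 2.28 from control levels of 10.60 and 11.38. Under CO2 the hemoglobin genes reached 13.58 and 13.65, near the highest signals of the CO2 samples (13.88 and 13.85), so the size of their rises is uncertain. RBOHB, for an NADPH oxidase, fell by 2.46. The list was called higher by camera, limma's test of a list against all other genes (adjusted p = 0.0364; adjusted p = 0.916 with an estimated correlation), and not without CO2 replicate 1 (0.094), CO2 replicate 2 (0.0619) or control replicate 1 (0.06), with the replicate block (0.0688), among probe sets at or above the median level (0.0533) or on ranks (0.147).

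More glycolysis genes rose than fell, with 8 of 17 members higher, 1 lower and 8 not passing (10 and 2 adjusted over the list alone). GAPC3, for a cytosolic glyceraldehyde-3-phosphate dehydrogenase, rose by 3.10 ± 0.13, GPI-B (glucose-6-phosphate isomerase) by 2.31, FBA1 (fructose-bisphosphate aldolase) by 2.30 and ENO1 (enolase) by 2.03 on the log2 scale. GAPC3 and ENO1 reached 13.26 and 13.24 under CO2, near the highest signals of the CO2 samples (13.88 and 13.85), so the size of their rises is uncertain. For each of these genes 2 of 3 probe sets were called higher. Camera called the list higher (adjusted p = 0.0106), but not with an estimated correlation (adjusted p = 0.916), and fry did not call it (adjusted p = 0.0686). Sucrose and starch breakdown went both ways, with 4 of 22 members higher, 5 lower and 13 not passing (5 and 5 adjusted over the list alone; camera adjusted p = 0.812). The alpha-amylase gene AMY1.3, also known as RAMY3D, rose 20.6-fold (log2 fold change 4.36 ± 0.82; 10.12 and 7.58 in CO2 replicates 1 and 2 against 4.46 and 4.51 in controls), and among the invertase genes CIN2 rose by 2.36 while CIN7 and CIN4 fell by 1.87 and 1.59. TPP1, for a trehalose-6-phosphate phosphatase, rose by 4.05 and the autophagy gene ATG5 by 2.33, in a list of sugar starvation and autophagy genes where 3 of 19 members rose, 1 fell and 15 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.26). Mitochondrial respiration had 3 of 21 members higher, 1 lower and 17 not passing (3 and 0 adjusted over the list alone; camera adjusted p = 0.184). ETF-QO and ETFA, which pass electrons from amino acid and fatty acid breakdown to the respiratory chain, rose by 1.17 and 0.88, and the alternative oxidase gene AOX1 fell by 1.09. As the mean of its probe sets ETFA gave 0.29 (adjusted p = 0.286). AOX1 has 1 probe set and kept its fold of -1.09 in that fit, where only its adjusted p changed, to 0.0544 in limma's test.

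The lists for photosynthesis and photorespiration were not called over all samples, although some single genes with roles in the chloroplast were among the largest falls. PORA, for the light-dependent protochlorophyllide reductase of chlorophyll synthesis, fell by 3.62 ± 0.82 with a wide spread in both groups (SD 1.29 in controls and 1.24 under CO2), PRIN2, a factor of plastid transcription, fell by 3.15 ± 0.21 and RNC1, a chloroplast splicing factor, by 2.90 ± 0.18. Of 13 light reaction genes, 1 rose, 4 fell and 8 did not pass (1 and 7 adjusted over the list alone; camera adjusted p = 0.107). FNR (ferredoxin-NADP reductase) fell by 1.35, RCABP89 (a chlorophyll-binding protein) fell by 1.33 and PSAH (a photosystem I subunit) fell by 0.84, and PSB28 rose by 1.06. In the photorespiration list 3 of 7 members fell, 4 did not pass and none rose (5 fell adjusted over the list alone). With the replicate block 1 of 7 fell, and without sets that can bind several transcripts 0 of 6 fell. The camera adjusted p was 0.0611, but 0.0389 after quantile normalization, 0.0393 as the mean of probe sets and 0.0477 with the crossed block. The glycolate oxidase genes GLO4 and GLO1 fell by 2.31 and 0.72, and GLO1 gave -0.12 (adjusted p = 0.623) as the mean of its probe sets. The only probe set of GLO4 can bind several transcripts. GDCSH, of the glycine cleavage system, fell by 0.73 on a probe set that can bind several transcripts but gave -0.03 (adjusted p = 0.885) on its other one. In the Calvin cycle list 1 of 6 members rose, 1 fell and 4 did not pass (1 and 1 adjusted over the list alone; camera adjusted p = 0.812). CFBP1, for the cytosolic fructose-1,6-bisphosphatase of sucrose synthesis rather than the cycle itself, rose by 1.92, and the triose phosphate translocator gene TPT fell by 0.94.

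More heat shock genes rose than fell as well, with 14 of 45 members higher, 5 lower and 26 not passing (19 and 6 adjusted over the list alone). The small heat shock protein genes HSP18.1, HSP17.4 and HSP24.1 rose 25.9-fold, 21.5-fold and 15.1-fold. The CO2 replicates differed from each other here, since HSP18.1 reached 11.63 in replicate 1 and 9.03 in replicate 2 against 5.46 and 5.82 in controls. HSFA2C (LOC4348646) rose 18.7-fold, and its record in the gene table also carries the name ARD1, so that the probe set cannot be assigned to the heat stress factor alone. Camera called the list higher (adjusted p = 0.0179), but not with an estimated correlation (adjusted p = 0.916), and fry did not call it (adjusted p = 0.23). In contrast, of 23 genes for folding in the endoplasmic reticulum, 1 rose, 1 fell and 21 did not pass (1 and 0 adjusted over the list alone, camera adjusted p = 0.812). ERDJ3A was higher by 1.16 and BZIP50 stood at -0.48. The BZIP50 change did not pass after quantile normalization (-0.35, limma adjusted p = 0.0914). BZIP50 has 1 probe set, and in the fit on means of probe sets its fold was the same but did not pass (limma adjusted p = 0.0708).

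CAT-A (LOC4328073), a catalase gene, had the largest fall among named genes, from 12.73 ± 0.10 to 8.62 ± 0.73 (log2 fold change -4.11 ± 0.35, adjusted p = 0.0034), and all 3 of its probe sets fell. It belongs to 45 antioxidant genes of which 4 rose, 12 fell and 29 did not pass (5 and 14 adjusted over the list alone; camera adjusted p = 0.447). The peroxiredoxin genes PRXIIE-1 and PRXIIE-2 fell by 1.86 and 1.66, and the glutaredoxin gene GRXS9 rose by 2.24.

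Hormone lists were mixed. Of 36 jasmonate genes 7 rose, 6 fell and 23 did not pass (9 and 7 adjusted over the list alone; camera adjusted p = 0.289, and 0.0462 without CO2 replicate 2). JAZ13, JAZ10 and JAZ6, which encode repressors of jasmonate responses, rose by 3.34, 2.60 and 2.45, and the lipoxygenase gene LOX5 by 2.65. CYP707A5, for an enzyme that breaks down abscisic acid, rose by 4.01. Kinase genes of that pathway went both ways. SAPK9 fell by 2.57 on a probe set that can bind several transcripts, while SAPK2 and SAPK6 rose by 0.91 and 0.81. The rise of SAPK2 did not pass with the replicate block (limma adjusted p = 0.0594). In the abscisic acid and dehydration list 4 of 33 members rose, 1 fell and 28 did not pass (2 and 1 adjusted over the list alone; camera adjusted p = 0.616, and 0.0434 without CO2 replicate 2), and without CO2 replicate 1 the counts were 2 higher and 6 lower. Of 21 ethylene genes 3 rose, 3 fell and 15 did not pass (3 and 3 adjusted over the list alone; camera adjusted p = 0.812). EIL1 (LOC4332697), for a transcription factor of ethylene signalling, fell by 3.36 and the ethylene receptor gene ERS2 by 2.43. The risen members ERF24 and ERF40, higher by 2.60 and 2.44, are also named DREB1A and DREB2A and are known for cold and drought responses.

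Many regulatory genes changed. Of 99 calcium and kinase signalling genes 28 rose, 17 fell and 54 did not pass (camera adjusted p = 0.168). The counts were 30 and 20 adjusted over the list alone, and 17 and 10 with the replicate block. CML15 and CIPK2 rose by 3.49 and 3.29, and CIPK10 and CML20 fell by 3.80 and 3.26. Camera called 3 lists of transcription factors higher, each with adjusted p = 0.916 with an estimated correlation. The NAC list's estimated correlation was 0.011, near the preset 0.01, yet camera's unadjusted p went from 0.0049 to 0.107. The value of 0.916 therefore cannot show whether members that vary together or a lack of power removed these calls. These lists hold only family members with a name in the tables used. Of 6 WRKY genes 3 rose and 3 did not pass (4 rose adjusted over the list alone; camera adjusted p = 0.0204, and 0.071 without CO2 replicate 1), led by WRKY71 at 2.04. Of 8 NAC genes 3 rose and 5 did not pass (4 rose and 1 fell adjusted over the list alone), led by NAC067 at 2.81. The NAC call (camera adjusted p = 0.0353) was lost without CO2 replicate 1 (0.0739), CO2 replicate 2 (0.0582) or control replicate 1 (0.06), with the replicate block (0.0515), among probe sets at or above the median level (0.0619), without sets that can bind several transcripts (0.111), as the mean of probe sets (0.0746) and on ranks (0.0572). Of 24 MYB and bHLH genes 5 rose, 1 fell and 18 did not pass (5 and 1 adjusted over the list alone; camera adjusted p = 0.0204), and MYB4 and MYB15 rose by 2.06 and 1.91 while MYBAS1 fell by 1.80. Outside these lists, cap2 rose 46.3-fold and the stress-associated zinc finger gene SAP5 rose 42.9-fold. In the glutathione S-transferase list GST1 rose 24.8-fold, from 6.81 ± 0.12 to 11.44 ± 1.35 (12.40 and 10.48 in CO2 replicates 1 and 2), on a probe set that can bind several transcripts, and the other 5 of 6 members did not pass (1 rose adjusted over the list alone; camera adjusted p = 0.812).

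More defence, metal and ion transport genes fell than rose. The same held over all genes, where 2218 rose and 3369 fell, and the balance in ion transport was close to that. Of 30 genes for pathogenesis-related proteins 4 rose, 12 fell and 14 did not pass (4 and 13 adjusted over the list alone; camera adjusted p = 0.0611, but 0.0426 without control replicate 2, 0.0476 after quantile normalization and 0.0345 with the crossed block). PBZ1 fell by 2.64 and the chitinase gene CHT5 by 2.17, while the chitinase gene CHT6 rose by 1.83 (adjusted p = 0.0515 where genes were taken as the mean of their probe sets). In phenylpropanoid and diterpenoid synthesis 1 of 43 members rose, 10 fell and 32 did not pass (1 and 5 adjusted over the list alone; camera adjusted p = 0.173), where the 10 became 5 as the mean of probe sets, 3 with the replicate block and 1 without CO2 replicate 1, and CAD8C fell by 2.59 while CAD3 rose by 1.61. Iron and metal handling had 4 of 56 members higher, 17 lower and 35 not passing (4 and 19 adjusted over the list alone; camera adjusted p = 0.242, and 0.0426 without control replicate 2). The iron transporter genes IRT2 and IRT1 went in opposite directions, by 3.03 and -2.47, and YSL13 fell by 2.67. Proton pumps and ion transport had 7 of 36 members higher, 10 lower and 19 not passing (8 and 12 adjusted over the list alone; camera adjusted p = 0.675), and the potassium transporter genes HAK17 and HAK13 fell by 3.42 and 1.86. Among 6 genes for bicarbonate and organic acid enzymes, ME6 and ACLA-3 rose by 1.19 and 0.89, NADP-ME2 fell by 1.32 and 3 did not pass (2 and 2 adjusted over the list alone; camera adjusted p = 0.812). No gene carried a carbonic anhydrase name in the tables used. Other named genes with large falls were OsCASPL2C2 (-3.08), Melibiase (-2.82), OsITPK3 (-2.76) and the expansin gene EXPB3 (-2.68).

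**Figure D2:**
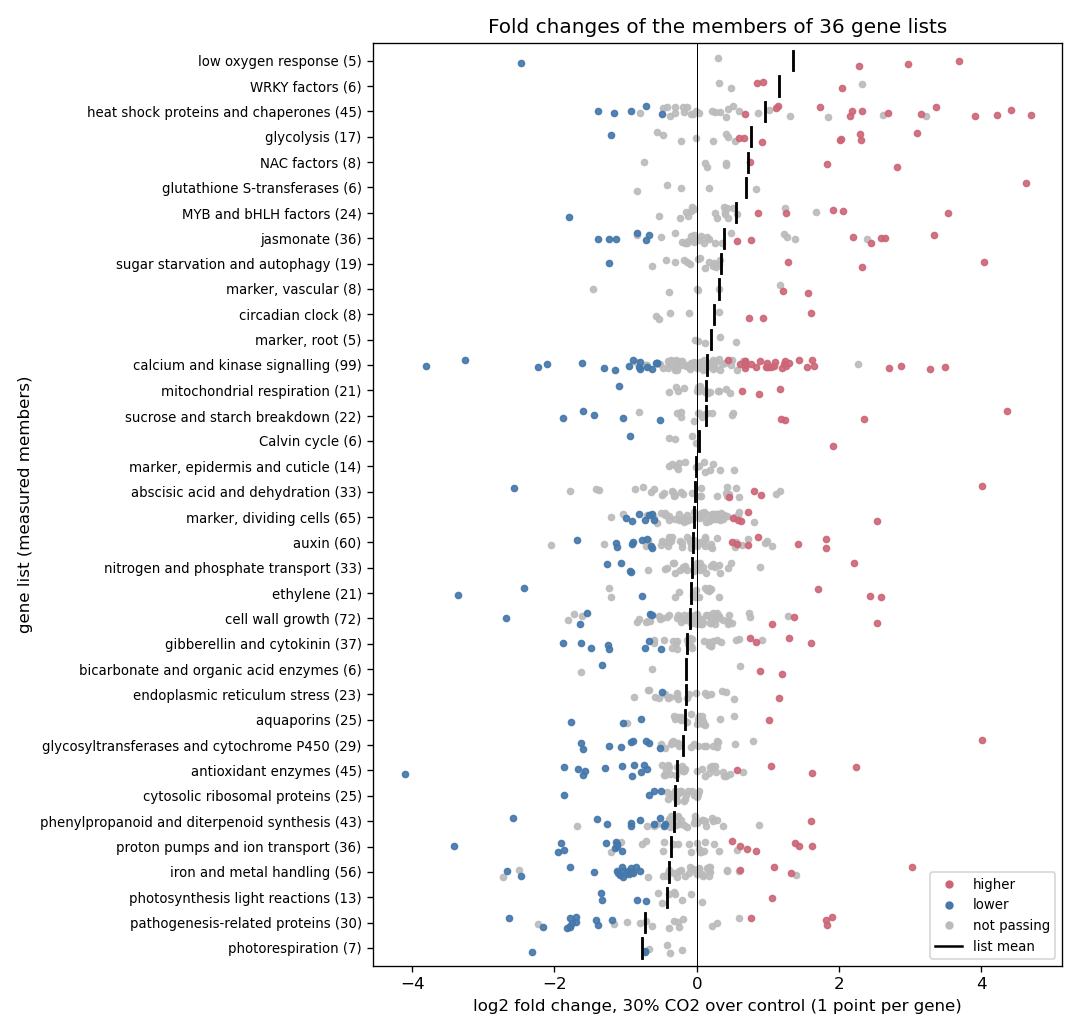
Log2 fold change, 30% CO2 over control, of each gene (points, horizontal axis) in 36 gene lists (vertical axis, with the number of measured members), coloured by whether the gene passed an adjusted p of 0.05 and in which direction. Black bars give list means, which ran from -0.776 for photorespiration to 1.36 for the low oxygen response.

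Few markers of particular leaf cells or of root passed. Of 65 dividing-cell genes 5 rose, 7 fell and 53 did not pass (2 and 5 adjusted over the list alone; camera adjusted p = 0.797), and KIN14N rose by 2.54 while ORC2 fell by 1.00. Of 8 vascular genes the sucrose transporter genes SUT2 and SUT4 rose, by 1.57 and 1.22, and 6 did not pass (2 rose adjusted over the list alone; camera adjusted p = 0.227). None of 14 epidermis and cuticle genes passed (camera adjusted p = 0.812), nor did any of 5 root genes (camera adjusted p = 0.459), and both counts were 0 adjusted over the list alone. At an unadjusted p of 0.05, limma gave 0 in either of these lists. With 2 samples per group the test rested on few degrees of freedom: leaving out either control sample left 0 genes past the threshold (9691 and 9246 probe sets at an unadjusted p of 0.05), and leaving out CO2 replicate 1 left 2218. Of the 4331 probe sets called at 2-fold, between 3820 and 4163 stayed past 2-fold in the same direction without any one sample. They were selected for their fold in these same samples, so most were bound to stay.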

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

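All alternatives were fixed before the data were examined except the crossed replicate block, added after. Every one of the 6583 calls kept its direction in each probe set fit that held it. Blocks, priors, filters and thresholds leave the fold change as it is. Only centring, quantile normalization or leaving out a sample could have turned a direction. With the replicate block, a fit in which samples share only a number, 1691 probe sets passed, all of them at least 2-fold, and 3666 genes. Same-numbered samples deviated with a correlation of -0.102, and with the numbers crossed 3478 probe sets passed. At adjusted p 0.01 there were 1528 and at 0.1 there were 9889, and limma's treat against 1.5-fold left 1714, each by construction of the threshold. Leaving out 1 sample, with 1 residual degree of freedom and the lone sample assumed to vary like the other group, gave 0 to 2477 probe sets, the same range at 2-fold, and 0 to 4568 genes. The 2477 came without CO2 replicate 2, and limma gave 0 without each other sample (9246 to 11506 at an unadjusted p of 0.05). Genes numbered 2218 without CO2 replicate 1 and 0 without either control. Centring, quantile normalization, filters and priors left between 5096 and 7315 probe sets. The set test called 6 lists, 0 with an estimated correlation and 4 to 9 elsewhere; the 4 of fry shared 2 with these, low oxygen and NAC factors, left out glycolysis (0.0686), heat shock (0.23), WRKY (0.122) and MYB and bHLH factors (0.173), and added ion transport and antioxidant enzymes as lower (0.049 each). Over all alternatives, low oxygen and NAC factors lost their call most often, with a camera adjusted p of up to 0.916, and the cause was not tested. Fry, which tests a list against no change, gave them an adjusted p of 0.000559 and 0.049. The excess of risen or of fallen members turned in 6 lists without CO2 replicate 1, 2 with the block, 1 after quantile normalization and 1 without CO2 replicate 2. No named gene reversed; the abscisic acid and dehydration list, not called at a mean of -0.028, turned to 0.393 (adjusted p 0.0434) without CO2 replicate 2 and gave -0.449, not called, without CO2 replicate 1. Of 139 named genes, 23 lost their call with the block, 42 without CO2 replicate 1, 21 without CO2 replicate 2 and 132 without either control. Signals near the floor have no detection calls, which limits folds of dim genes.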

Other observations

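Further lists fixed beforehand held smaller or mixed changes. Of 60 auxin genes 7 rose, 9 fell and 44 did not pass (6 and 9 adjusted over the list alone, 12 and 11 after quantile normalization, 4 and 3 with the replicate block, 2 and 1 without CO2 replicate 1; camera adjusted p = 0.824), and on the log2 scale the transport genes PIN5 and PIN3A rose by 1.82 and 1.81 while IAA10 fell by 1.68. Of 37 gibberellin and cytokinin genes 4 rose, 8 fell and 25 did not pass (5 and 8 adjusted over the list alone; camera adjusted p = 0.983), and the cytokinin-activating genes LOGL1 and LOGL3 went in opposite directions, by 1.60 and -1.88. Cell wall growth had 3 of 72 members higher, 5 lower and 64 not passing (3 and 2 adjusted over the list alone; camera adjusted p = 0.709), with CSLC9 at 2.53 and EXPA1 at -1.64. In the cytochrome P450 list 1 of 29 members rose, 9 fell and 19 did not pass (camera adjusted p = 0.417). The counts were 1 and 9 adjusted over the list alone, and 1 and 3 with the replicate block. CYP734A6 and CYP701A19 fell by 1.62 and 1.59. Of 25 cytosolic ribosomal protein genes 4 fell, led by RPL18 at -1.87, and 21 did not pass (2 fell adjusted over the list alone; camera adjusted p = 0.0965, but 0.0317 without control replicate 2 and 0.0389 after quantile normalization). The clock genes PCL1, LHY and PRR73 rose by 1.60, 0.93 and 0.73, and 5 of 8 in that list did not pass (3 rose adjusted over the list alone; camera adjusted p = 0.447), but as the mean of their probe sets LHY gave 0.56 (adjusted p = 0.0675) and PRR73 gave 0.67 (adjusted p = 0.0698), which left 1 higher. Nitrogen and phosphate transport had 1 of 33 members higher, 4 lower and 28 not passing (1 and 4 adjusted over the list alone; camera adjusted p = 0.917), with SPX2 at 2.21 and the urea transporter gene DUR3 at -1.26. Aquaporins had 1 of 25 members higher, 3 lower and 21 not passing (0 and 0 adjusted over the list alone; camera adjusted p = 0.812), with PIP2;7 at -1.76 and PIP2;1 at 1.02, the latter lower and not past the threshold as the mean of its probe sets (0.37, adjusted p = 0.16) or without sets that can bind several transcripts (0.89, adjusted p = 0.0635). None of the 3 class III peroxidase genes with a name in the tables used passed in limma's test, either way of adjusting, and 0 did at an unadjusted p of 0.05.

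Families that share a symbol were tested after the data were seen, and their members named here were chosen after their values were seen. Of 24 groups of genes with a shared symbol and at least 8 members, 20 were distinct and the others repeated members of these. Over the 20, camera called the stress-associated zinc finger proteins (adjusted p = 0.00697), with 3 of 13 members higher and none lower, and called WNK kinases and protein phosphatases 2C at an adjusted p of 0.0461 each, which was 0.0554 over all 24; with an estimated correlation all 3 had an adjusted p of 0.616. SAP5, ISAP1 and SAP17 rose by 5.42, 1.42 and 1.92. Of 9 genes under the WNK symbol 3 rose, led by WNK5 at 2.34, and of 55 protein phosphatase 2C genes 14 rose and 2 fell, led by OsPP2C45 at 3.35. Beta-glucosidase genes went both ways, with 2 of 27 higher, led by BGLU31 at 3.75, and 7 lower (camera adjusted p = 0.306).

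The tests on oxygen, on ethylene and on the share of calls without CO2 replicate 2, at a stricter threshold or after quantile normalization were chosen after their results were seen. The first pattern is that CO2 replicate 1 lay further from the controls than CO2 replicate 2, with a median log2 change of 1.61 against 1.43 over probe sets called at 2-fold. For an array-wide compression of replicate 2, uncalled probe sets were checked, and their SD in replicate 2 was 1.03 times that in replicate 1. RMA, named in the labels, brings arrays to a similar distribution, so a ratio near 1 was likely either way. The check therefore cannot decide on compression. Control RNA mixed into replicate 2 is argued against as the whole cause, but only weakly. The median loss of log2 fold among 640 probe sets that rose at least 4-fold was 0.537 and would need a control share of 31.1%. The 492 probe sets that fell at least 4-fold gave 3.13% (3.23% and 3.03% against either control alone), which predicts a loss of 0.0459. Requiring a 4-fold fall favours probe sets with a small share, and replicates give no spread here, as the pattern is in 1 sample. A weaker response of the same genes stays open, since the 70.4% of the called probe sets that rose and 65.6% of those that fell with the smaller change in replicate 2 restate the pattern and decide no cause. Differences in gas level or sampling between the replicates stay open and were not tested.

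The second pattern is the rise of the fermentation genes under 30% CO2. A sealed bag may also hold less oxygen than air, and the 3 fermentation genes that rose cannot be told apart between low oxygen and CO2 itself, because the gas goes with the group, no oxygen value is given and it is not stated whether controls were bagged. Ethylene gathered in the bag was checked on the receptor genes ERS1 and ERS2, which ethylene is known to raise. Both were lower, with a mean log2 fold change of -1.60. CO2 itself may change these genes or their response to ethylene, so the check cannot decide and ethylene stays open. A direct effect of CO2 or of cell acidity stays open as an untested hypothesis.

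The third pattern is that more probe sets fell than rose, with 41.1% of the called ones higher. For compression of dim probe sets, the share was taken among probe sets at or above the median level, and it was again 41.1% higher. Of the 6583 called probe sets, 6206 were also called there, so the share was bound to stay close. The excess of falls therefore does not rest on probe sets below the median level. Probe sets just above that level can still be dim, so the check cannot decide on compression, which stays open. An offset between the samples' scales stays open, because centring on the median, which gave 37.6% higher, was bound to lower the share where the CO2 medians (3.92 and 3.88) exceed those of the controls (3.85 and 3.86), while quantile normalization gave 44.6%, and 45.9% at 2-fold. Without CO2 replicate 2 the share was 50.2% of 2477 probe sets but 37.2% of 4568 genes, and at adjusted p 0.01 it was 46.9% of 1528 probe sets. No biological explanation was tested.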
